A study of Mus musculus with 8 samples.

How the data were processed

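Total RNA from 8 mouse embryonic stem cell samples was labelled and hybridised to Affymetrix mouse expression arrays, per the labels' protocols. The values used here are the deposited log2 normalized intensities of 45101 probe sets per array, made by the authors with RMA per the submitters' processing notes. RMA subtracts background, normalizes the arrays to each other by quantiles and summarises the probes of a probe set on the log2 scale; its version is not given in the sources used here. Quantile normalization holds the overall distribution of all arrays alike, so a change of total RNA content or a shift of most genes in a group is not visible, and folds between dim and bright signals are compressed. No detection calls were used. Column medians of 5.96 to 6.02 and maxima of 15.0 to 15.1 fit values on a log2 scale, and every value column was matched to a sample. Genome coordinates were not used here beyond the chromosome of the targeted genes.

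Samples were grouped by genotype and line labels into wild-type, exon 2 mutant, Hprt knockout and trap, with 2 arrays each. The exon 2 mutant arrays were registered apart from the others, and no label gives a batch, so a batch between lines cannot be told apart from the lines. Probe sets were paired with genes through the platform annotation given. Of the probe sets, leaving out 64 controls, 34945 had 1 symbol, 932 had several and 9160 had none, and probe sets with several symbols or none were not named. Of those with 1 symbol 34754 matched the gene table by Entrez ID, and 0 symbols needed an update. The 18193 genes were each represented by the probe set with the highest mean over the 8 arrays, a choice that mattered for the 9010 genes with several. A gene was tested when its value lay above the 40th percentile of the array on at least 2 of the 8 arrays, a level of log2 5.35 on average, which left 13819 genes.

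Differences were tested with limma 3.58.1 in R 4.3.3. A model of 4 group means was fitted to all 8 arrays (lmFit and eBayes), so that the groups shared 1 estimate of the spread, with 4 residual degrees of freedom and 6.86 after moderation. P-values are two-sided and were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. An exact permutation test of 2 against 2 arrays cannot go below p = 0.333, so no gene was tested that way. The comparisons were exon 2 mutant against wild-type, trap against Hprt knockout, Hprt knockout against wild-type, trap against wild-type, and the difference between the effects of both mutations. Values are given as log2 fold change ± standard error. Overlap of calls was set against the product of both call counts divided by the genes tested. For comparisons that share the wild-type arrays, 100 simulations of unchanged groups gave the correlation and covariance that shared controls produce with no effect.

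Gene lists, comparisons, tests, the rule for named genes and most alternatives were fixed before the data were examined. The 25 lists were written from general knowledge and tested with camera for the 3 comparisons of lines with their controls and of both controls, at a preset correlation of 0.01 and with at least 5 tested members, adjusted over the lists. Camera with an estimated correlation kept 1 of 10 calls for the exon 2 mutant (feeder fibroblast), 2 of 9 for trap against Hprt knockout and 2 of 8 for Hprt knockout against wild-type (feeder fibroblast and interferon response in both). The estimate lay above the preset for pluripotency (0.063) and immediate early genes (0.079). It lay below it for primitive endoderm (-0.016), cell cycle (-0.0079) and interferon response (-0.011). A higher correlation therefore does not account for calls lost by these lists. The feeder fibroblast estimate (-0.0033) was below the preset too, yet in the exon 2 mutant its camera adjusted p went from 2.80e-11 to 0.0327. The estimated setting thus changes more than the correlation, and a lost call does not show correlated genes. Fry, which tests whether a list's genes move on balance in a common direction and does not compare them with other genes, called 23, 23 and 25 lists. The lists were pluripotency network, primed epiblast, 2-cell-like state, primitive endoderm, mesoderm and primitive streak, neuroectoderm, trophoblast, germ line, feeder fibroblast, Williams-Beuren interval, purine salvage and synthesis, PI3K-AKT pathway, TGF-beta and BMP pathway, genes tied to TFII-I in earlier work, imprinted genes, sex-linked genes, endoplasmic reticulum and amino acid stress, hypoxia and glycolysis, cell cycle, p53 targets, interferon response, immediate early, cholesterol synthesis, cytoskeleton and adhesion, and ribosomal proteins.

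Genes were named by rule. Named were Gtf2i, Hprt and members of the Williams-Beuren interval, and per comparison the 10 largest rises and falls among genes past the threshold whose arrays did not overlap between groups, leaving out clone and predicted names. Per list and tested comparison up to 4 passing members with the smallest adjusted p were named, or, where none passed, up to 2 with the largest change. Of genes changed the same way by both mutations the 10 per direction with the largest smaller change were named, and of genes whose effect differed the 5 largest per direction. Exceptions are the feeder markers named for trap against wild-type and the genes shared by the exon 2 mutant and the trap line against wild-type, which were chosen after their values were seen.

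The model was tested on simulated data. For exon 2 mutant against wild-type, with 200 of 13819 genes changed, it recovered 62.5% of changes of log2 0.5, 90% of changes of log2 1 and all of log2 2, with 3.10%, 6.25% and 6.54% of calls false. In the simulated list test the shifted list was called, and 1 of 24 other lists was called as well. Alternatives were no filter and a filter at the 60th percentile, the mean of a gene's probe sets or all probe sets in place of 1 per gene, repeated quantile normalization, median centring, cyclic loess, a trended robust prior, only the compared arrays in the fit, the replicate number as a block, stricter thresholds and each array left out in turn. Exchanged controls, crossed replicate numbers and a fit without the Hprt knockout arrays were added after seeing the data. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.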

Results

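Gene expression was measured in mouse embryonic stem cells that differed at Gtf2i or at Hprt, on 8 Affymetrix mouse expression arrays with 45101 probe sets each. Gtf2i, on chromosome 5, encodes the transcription factor TFII-I, and its human counterpart lies in the interval deleted in Williams-Beuren syndrome. Hprt, on chromosome X, encodes a purine salvage enzyme. The arrays fell into 4 groups of 2. The wild-type group carried no mutation in its label, and the labels did not say which line it was. The exon 2 mutant was a gene-targeted derivative of the R1 stem cell line that lacked exon 2 on an allele of Gtf2i. The Hprt knockout carried a mutation of Hprt and none of Gtf2i. The trap line was a heterozygous gene-trap insertion in Gtf2i, made in the AB2.2 stem cell line, and its genotype label carried the Hprt mutation as well. All cells were grown with leukaemia inhibitory factor on a layer of feeder cells, so fibroblast markers were followed beside every gene group. Median log2 intensity lay between 5.96 and 6.02 on the 8 arrays. Across the 13819 tested genes, with 1 probe set each, arrays of the same group correlated at 0.997 to 0.998, and the SD of the difference between them was 0.130 to 0.169. The Hprt knockout arrays correlated least with the others, at 0.866 with wild-type, against 0.978 to 0.979 between trap and wild-type and 0.967 to 0.969 between exon 2 mutant and wild-type. The number of arrays per group, 2, limits the precision. The labels call the arrays biological replicates without saying whether they came from separate cultures, so p-values measure only the spread between these arrays.

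The targeted genes were examined on every array. Hprt had a mean log2 intensity of 12.08 in wild-type, 12.25 in the exon 2 mutant, 10.04 in the Hprt knockout and 10.74 in the trap line (n = 2 arrays each). It was lower in both lines labelled as Hprt mutant, by log2 -2.05 ± 0.05 (SE) in the Hprt knockout against wild-type (adjusted p = 6.19e-08) and by log2 -1.34 ± 0.05 in the trap line against wild-type (adjusted p = 9.09e-06). The trap line lay 0.71 ± 0.05 above the Hprt knockout (adjusted p = 1.36e-05), as did its feeder markers, whose list median was higher by log2 3.95. The exon 2 mutant differed from wild-type by 0.17 (adjusted p = 0.0209), a call that was lost under cyclic loess scaling, with only the compared arrays in the fit, and whenever any of the 4 compared arrays was left out. Gtf2i, on its brightest probe set, had means of 10.12 in wild-type, 10.48 in the exon 2 mutant, 10.90 in the Hprt knockout and 10.09 in the trap line. It was lower in the trap line than in the Hprt knockout by log2 -0.82 ± 0.05 (adjusted p = 9.87e-06), and its difference between trap and wild-type, -0.03, did not pass (adjusted p = 0.638). In the exon 2 mutant Gtf2i was higher than in wild-type, by 0.36 ± 0.05 (adjusted p = 0.00102), and in the Hprt knockout it was higher by 0.78 (adjusted p = 9.65e-06). Its second probe set gave the same directions where it passed, at log2 0.64 for exon 2 mutant against wild-type, -1.19 for trap against Hprt knockout and 1.34 for Hprt knockout against wild-type. The other 2 probe sets of Gtf2i lay below the filter level in all groups and no difference passed there. Where the probes lie relative to exon 2, to the trap insertion or to the Hprt mutation was not analysed here, so the Gtf2i signal checks neither label. Hprt was lower in the lines labelled as mutant but stayed far above the filter level there, on average log2 5.35, so its signal does not show a loss of the transcript.

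**Figure D1:**
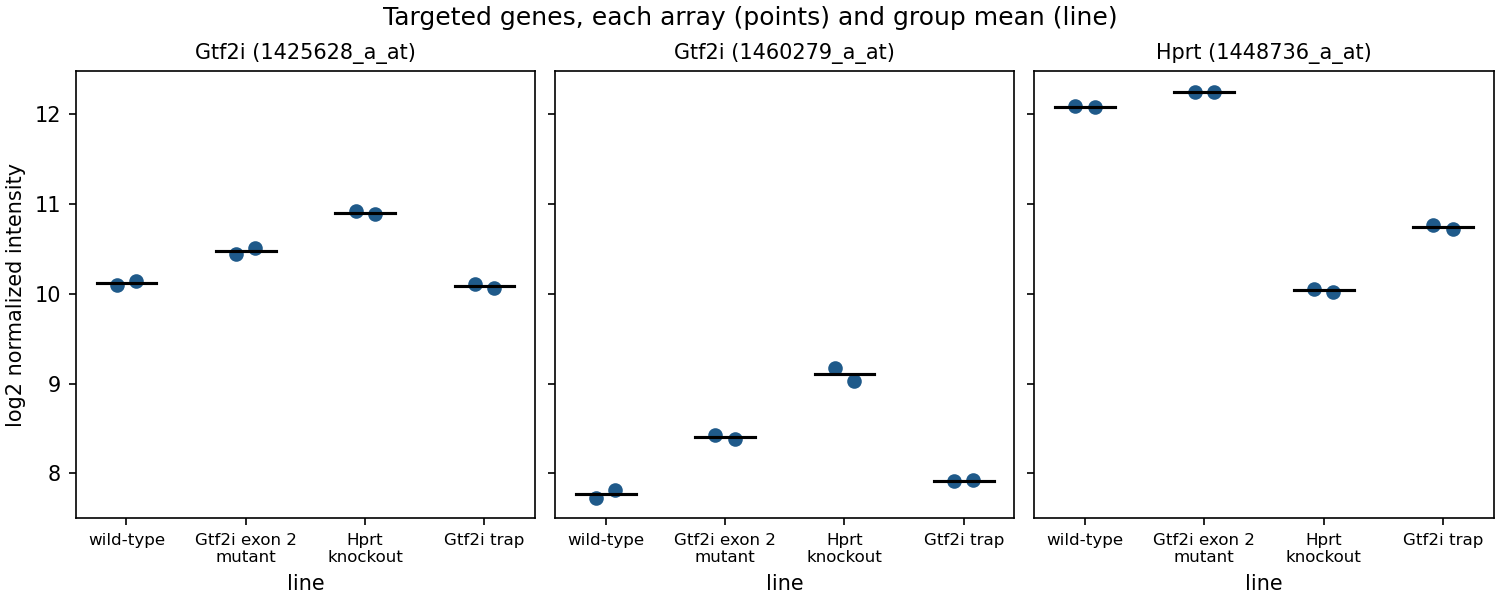
Log2 normalized intensity (vertical axis) of Gtf2i on 2 probe sets and of Hprt on 1 probe set in the 4 lines (horizontal axis), with each array as a point and each group mean as a line. Hprt was lowest in the Hprt knockout (mean 10.04) and the trap line (10.74), and Gtf2i on its brightest probe set (left) was highest in the Hprt knockout (10.90).

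The exon 2 mutant was compared with wild-type to ask which genes differ when exon 2 is missing from an allele of Gtf2i. The wild-type line is not named, and the exon 2 mutant arrays were registered apart. The comparison therefore also holds any difference of line or batch, which cannot be told apart from the mutation. Genes of the pluripotency network were higher and immediate early genes, primitive endoderm genes and fibroblast markers were lower in the mutant (log2 fold change ± SE, n = 2 against 2 arrays). Of these 4 list calls only that of the fibroblast markers held when camera estimated the correlation between genes. The largest rises were in Chac1, a glutathione-degrading enzyme of the amino acid stress response (3.68 ± 0.08, adjusted p = 1.35e-06) and in the transcription factor gene Myb (3.38 ± 0.19, with wild-type below the filter level). Large rises were also seen in Mid1 (3.16 ± 0.09) and in Lefty1, an inhibitor of Nodal signalling (3.07 ± 0.05, adjusted p = 8.34e-07). Otx2, a transcription factor of the primed epiblast, rose by 3.01 ± 0.08 (adjusted p = 2.37e-06), and Ccdc160, Csrnp3, Fut9, Trib3 and Trpm1 rose by 2.64 to 3.30. The largest falls were in the growth-factor-induced transcription factor gene Egr2 (-4.00 ± 0.14) and in Serpinb2 (-3.53 ± 0.13), both with the exon 2 mutant below the filter level. The related gene Egr1 (-2.99 ± 0.05, adjusted p = 8.34e-07) fell too, as did Ccn2, a secreted matrix protein gene (-2.80 ± 0.06, adjusted p = 1.34e-06). Htr1b, Chsy3, Asb5, Cdh19, Timp3 and Tnfrsf11b fell by -3.31 to -2.74. Chsy3 and Cdh19 fell to below the filter level too, and Ccdc160 and Csrnp3 rose from below it in wild-type. A fold against a group below the filter level, on average log2 5.35, depends on the array background. Chac1, Lefty1, Otx2, Trib3, Egr1 and Egr2 moved the same way in the Hprt knockout against wild-type, with values given below, while Mid1 went the other way. The Hprt knockout has no Gtf2i mutation, so the changes of the former genes are not tied to exon 2 by this comparison.

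Of 24 tested members of the pluripotency network, 19 rose, 1 fell and 4 did not pass, with the same counts adjusted over the list alone, and the list median was 0.32. Klf2 (1.17), Prdm14 (1.30), Nr0b1 (0.85) and Sall4 (0.80) rose, and camera called the list higher (adjusted p = 9.62e-05, and adjusted p = 0.129 with an estimated correlation). The primed epiblast list had 6 rises and 4 falls among 12, also adjusted over the list alone (adjusted p = 0.775). Lef1 (1.56) and Zic2 (1.52) were up and the activin inhibitor Fst (-1.77) down. All 5 tested genes of the 2-cell-like state fell, also adjusted over the list alone, among them Pramel7 (-2.13) and Pramel6 (-1.56), for a list median of -0.74 (adjusted p = 0.00106, and adjusted p = 0.159 with an estimated correlation). Of 21 primitive endoderm genes 14 fell, 15 adjusted over the list alone, and 1 rose. The proteoglycan gene Srgn (-2.22) and the basement membrane genes Lama1 (-1.50) and Col4a1 (-0.87) were lower and the lipoprotein gene Apoe was higher (0.95), with a list median of -0.73 (adjusted p = 0.000139, and adjusted p = 0.0728 with an estimated correlation). The feeder fibroblast markers fell in 27 of 28 cases, also adjusted over the list alone, with a median of -0.59 and low values in Ccn2, Ccn1 (-2.67), Thbs1 (-2.22) and Tagln (-1.33). Its call held with an estimated correlation (adjusted p = 2.80e-11, and adjusted p = 0.0327 with an estimated correlation).

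Immediate early genes fell in 15 of 18 cases, also adjusted over the list alone, and 1 rose, with a list median of -0.87, beside the feeder median of -0.59. Egr1, Egr2, the nuclear receptor gene Nr4a1 (-2.48) and Ier3 (-1.12) were among them (adjusted p = 1.52e-07, and adjusted p = 0.0728 with an estimated correlation). Hypoxia and glycolysis genes rose in 19 of 24 cases and fell in 4, also adjusted over the list alone (median 0.59, adjusted p = 0.000350, and adjusted p = 0.0728 with an estimated correlation). Bnip3 (2.14), the prolyl hydroxylase gene Egln3 (1.77) and Ddit4 (1.56) were up and Adm (-0.87) down. Cell cycle genes rose in 20 of 29 cases and fell in 3, also adjusted over the list alone, including Cenpe (0.92), Bub1 (0.90), Cdc6 (0.89) and Cenpf (0.79) (median 0.42, adjusted p = 0.000459, and adjusted p = 0.0728 with an estimated correlation). Of 21 interferon response genes 14 fell, 15 adjusted over the list alone, and 3 rose (adjusted p = 0.00114, and adjusted p = 0.0728 with an estimated correlation). The class I histocompatibility genes H2-D1 (-0.89) and H2-K1 (-0.82) and B2m (-0.55) were lower and Ifitm1 higher (0.58), beside the fall of the feeder markers. Of 22 cytoskeleton and adhesion genes 7 rose and 13 fell, also adjusted over the list alone. Icam1 (1.07) and Cdh1 (0.93) were up and Krt18 (-1.32) and Itga5 (-1.23) down. Its call (adjusted p = 0.0386, and adjusted p = 0.470 with an estimated correlation) was lost in 5 other settings, with adjusted p up to 0.0681.

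The TGF-beta and PI3K-AKT lists were written because the study is recalled to have dealt with these pathways, so their counts are not independent evidence of a direction. TGF-beta and BMP genes fell in 19 of 39 cases and rose in 6, also adjusted over the list alone, beside the feeder markers (list median -0.17, adjusted p = 0.0178, and adjusted p = 0.501 with an estimated correlation). The BMP target Id1 (-2.72 ± 0.05) and the ligand gene Tgfb2 (-1.51) fell, while the Nodal inhibitors Lefty1 and Lefty2 (2.42 ± 0.06) rose. Of 29 PI3K-AKT genes 12 rose and 9 fell, 12 and 10 adjusted over the list alone (adjusted p = 0.813). Its median of 0.09 turned negative under cyclic loess, which moved the median of all genes by -0.05, and stayed positive relative to all genes. The phosphatase gene Inpp5d (1.30), Foxo3 (0.91), Irs1 (0.70) and Tcl1 (0.69) were higher. Among 14 genes tied to TFII-I in earlier work 5 rose and 5 fell, 5 and 7 adjusted over the list alone (adjusted p = 0.650). Brca1 (1.08) and Nsd1 (1.00) were higher and Fos (-1.71) and the chaperone gene Hspa5 (-0.77) lower. In the Williams-Beuren interval 12 of 23 genes rose and 2 fell, also adjusted over the list alone (median 0.19, adjusted p = 0.253). Mettl27 (0.82), Gtf2ird1 (0.71), Baz1b (0.57) and Rfc2 (0.47) were higher and the elastin gene Eln (-0.97) lower. A second probe set of Gtf2ird1, also above the filter level, gave 0.15 and did not pass (adjusted p = 0.464 over all probe sets). Stress genes of the endoplasmic reticulum and amino acid response rose in 12 of 20 cases and fell in 7, 12 and 8 adjusted over the list alone (median 0.39, adjusted p = 0.253). Chac1, Trib3 (2.76), Ddit3 (1.27) and Herpud1 (1.11) were higher.

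No further list was called in this comparison. Counts of rises and falls, which were equal when adjusted over the list alone except for the ribosomal proteins, were 5 and 7 of 17 for neuroectoderm (adjusted p = 0.253), with Neurod1 at 1.48 and Nefm at -2.55. They were 1 and 1 of 10 for mesoderm (adjusted p = 0.253), with Bmp4 at -1.14. Trophoblast genes had 2 and 2 of 10 (adjusted p = 0.777), with a median of 0.03 against a negative mean and test. Germ line genes had 7 and 4 of 16 (adjusted p = 0.323), with Mael at 1.24. The p53 targets had 8 rises and 9 falls among 19 (adjusted p = 0.514), with Plk2 at -1.03 and Fas at -1.31. Cholesterol synthesis had 2 and 5 among 16 (adjusted p = 0.253), with Dhcr7 at 0.79 and Hmgcs1 at -0.59. Purine genes had 10 and 5 among 22 (adjusted p = 0.660), with Prps2 at 0.72 and Adsl at 0.64. Imprinted genes had 9 and 5 among 23 (adjusted p = 0.931), with Plagl1 at -0.75. The medians of both lists (0.10 and 0.08) turned negative under cyclic loess with the shift of all genes and stayed positive relative to them. Of 6 genes linked to the sex chromosomes 3 fell and none rose (adjusted p = 0.115), with Kdm5d at -0.39. Ribosomal protein genes had 2 rises and 1 fall among 14, and none of either adjusted over the list alone (adjusted p = 0.650), with Rpl8 at 0.17 and Rps6 at -0.21. By limma, 7674 of 13819 tested genes passed, 4485 higher and 3189 lower in the exon 2 mutant, and 750 of them differed at least 2-fold, 409 higher and 341 lower. Cyclic loess changed the split to 3676 higher and 4019 lower.

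The trap line was compared with the Hprt knockout, its matched control by genotype label alone, to ask which genes differ with the trap in Gtf2i. These arrays correlated at 0.888 to 0.889, below the 0.978 to 0.979 between trap and wild-type. The comparison also holds any difference of line and of feeder signal, which cannot be told apart from the trap. Fibroblast markers and interferon response genes were far higher in the trap line. The chemokine gene Cxcl5 was higher by log2 8.86 ± 0.08 (adjusted p = 4.61e-09, n = 2 against 2 arrays). The acute phase gene Saa3 was higher by 7.64 ± 0.12, the chemokine gene Ccl2 by 7.43 ± 0.05 and the matrix metalloproteinase gene Mmp3 by 7.00 ± 0.05. Ccl8, Agtr2, Mmp13, Ifit1, Lum and Steap4 rose by 7.04 to 7.50 from a level in the Hprt knockout below the filter. The largest falls were in the Notch ligand gene Dll1 (-3.49 ± 0.16, adjusted p = 2.11e-06), Insm1 (-3.34 ± 0.10), Chac1 (-3.09 ± 0.08) and the keratin gene Krt18 (-3.07 ± 0.09). Car4, Frem2, Neurod1, Krt8, Ccno and Cldn6 fell by -2.94 to -2.78. Of the genes named for this comparison, Cxcl5, Usp18, Ifit3, Vcam1, Zic1, Gda and Xdh also rose from below the filter level in the Hprt knockout, and Insm1 and Frem2 fell to below it in the trap line, so these folds depend on the array background. Of 28 feeder fibroblast markers 26 rose and 1 fell, 26 and 2 adjusted over the list alone (adjusted p = 5.41e-17, and adjusted p = 0.0148 with an estimated correlation). The collagen gene Col3a1 was at 4.87 ± 0.05, Prrx1 at 5.03, Serpinf1 at 4.74 and Lum at 7.22. The median of all tested genes was -0.13 and moved by 0.14 under cyclic loess, so list medians of this comparison are given relative to all genes. That of the feeder markers was 4.08, and on this scale no list median changed sign under another scaling.

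With the feeder markers at 4.08, interferon response genes rose in 19 of 21 cases and none fell, also adjusted over the list alone (median 2.36, adjusted p = 2.68e-11, and adjusted p = 0.0191 with an estimated correlation). Usp18 was at 6.46, Ifit3 at 5.54 and B2m at 3.37. TGF-beta and BMP genes rose with them in 26 of 39 cases and fell in 10, also adjusted over the list alone. The receptor gene Tgfbr2 (4.58), Inhbb (3.17) and Tgfb2 (2.08) were higher and Lefty1 (-2.59) lower (median 0.51, adjusted p = 9.44e-05, and adjusted p = 0.398 with an estimated correlation). PI3K-AKT genes rose in 15 of 29 cases and fell in 9, also adjusted over the list alone and beside the feeder markers (median 0.43, adjusted p = 0.0304, and adjusted p = 0.398 with an estimated correlation). Irs1 (3.62), the cyclin gene Ccnd1 (2.16), Pik3r1 (1.93) and Akt1 (1.53) were higher. That call was lost in 1 other setting (adjusted p = 0.0851). As stated for the exon 2 mutant, neither pathway list is independent evidence of a direction. Cholesterol synthesis genes rose in 11 of 16 cases and fell in 2, also adjusted over the list alone (median 0.53, adjusted p = 0.00167, and adjusted p = 0.398 with an estimated correlation). Hsd17b7 (2.10), Sc5d (1.08) and Msmo1 (0.91) were higher. Hypoxia and glycolysis genes rose in 13 of 24 cases, 14 adjusted over the list alone, and fell in 6 (median 0.39, adjusted p = 0.0304, and adjusted p = 0.326 with an estimated correlation). Adm (2.05) and P4ha1 (1.34) were higher and Ddit4 (-1.76) lower. The call was lost under cyclic loess (adjusted p = 0.0579).

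Cell cycle genes fell in 25 of 29 cases and rose in 3, also adjusted over the list alone (median -0.46, adjusted p = 0.00117, and adjusted p = 0.112 with an estimated correlation). The mitotic genes Aurka (-1.20) and Ccnb2 (-1.07) were lower and the D-type cyclin genes Ccnd2 (4.02) and Ccnd1 higher. Germ line genes fell in 14 of 16 cases and rose in 1, also adjusted over the list alone (median -1.07, adjusted p = 0.00352, and adjusted p = 0.417 with an estimated correlation). Dppa3 (-2.53), Mael (-1.58), Slc25a31 (-1.42) and Taf7l (-1.35) were lower. Trophoblast genes fell in 9 of 10 cases and rose in 1, also adjusted over the list alone (median -0.80, adjusted p = 0.0304, and adjusted p = 0.326 with an estimated correlation). Krt8, Krt18, Tfap2c (-2.17) and Krt19 (-1.39) were lower. The fall of these 3 lists stood beside the rise of the feeder markers. Pluripotency genes went both ways, with 10 rises and 10 falls among 24, also adjusted over the list alone (adjusted p = 0.689). Fgf4 (-1.18) and Dppa3 were lower and Tfcp2l1 (1.14) and Klf4 (0.92) higher. Relative to all genes the list's median (0.11) and its test were positive and its mean negative. The primed epiblast list had 4 rises and 7 falls among 12, also adjusted over the list alone (adjusted p = 0.668). Pou3f1 (-2.69), the DNA methyltransferase gene Dnmt3a (-2.60) and Otx2 (-1.98) were lower and Fst (2.35) higher.

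The remaining lists were not called. Primitive endoderm genes had 7 rises and 10 falls among 21, 7 and 12 adjusted over the list alone (adjusted p = 0.806), with Sparc at 1.95 and Lama1 at -2.00. Endoplasmic reticulum and amino acid stress genes had 7 and 11 among 20, 8 and 11 adjusted over the list alone (adjusted p = 0.668), with Trib3 at -2.36 and Nupr1 at 2.39. Mesoderm genes had 4 and 2 among 10, 4 and 1 adjusted over the list alone (adjusted p = 0.308), with Pdgfra at 2.57. Ribosomal protein genes had 0 and 2 among 14, and none of either adjusted over the list alone (adjusted p = 0.839), with a median of 0.08 against a negative mean and test. In the other lists the counts were equal when adjusted over the list alone. Immediate early genes had 8 rises and 5 falls among 18 (adjusted p = 0.149), with Ier3 at 3.32 and Jun at 1.88. Cytoskeleton and adhesion genes had 12 and 9 among 22 (adjusted p = 0.159), with Vcam1 at 6.18 and Vim at 2.07, and p53 targets had 8 and 6 among 19 (adjusted p = 0.229), with Fas at 2.98. Neuroectoderm had 8 and 5 among 17 (adjusted p = 0.161), with Zic1 at 3.97 and Neurod1 at -2.86. The 2-cell-like state had 3 and 1 among 5 (adjusted p = 0.582), with Pramel6 at 1.34. The Williams-Beuren interval had 3 and 14 among 23 (adjusted p = 0.165), with Cldn4 at -1.82, Tbl2 at -0.88, Bud23 at -0.76 and Rfc2 at -0.72. Gtf2ird1 (-0.18) lost its call under cyclic loess and in fits that left out an array, and its second probe set, at 0.13, did not pass. Purine genes had 5 and 12 among 22 (adjusted p = 0.668), with Gda at 5.01, Xdh at 3.92 and Gart at -1.27. Imprinted genes had 7 and 13 among 23 (adjusted p = 0.839), with Igf2 at 4.74 and the feeder marker Dcn at 6.78. In both lists the median and test were negative and the mean positive. Genes tied to TFII-I had 5 and 7 among 14 (adjusted p = 0.719), with Ezh2 at -0.66 and Usf1 at -0.67. Sex-linked genes had 1 and 4 among 6 (adjusted p = 0.716), with the X-inactivation RNA gene Xist at 1.75. By limma 9449 genes passed, 3675 higher and 5774 lower in the trap line, with 2104 differing at least 2-fold, 1420 higher and 684 lower. Cyclic loess changed the split to 4690 and 4244.

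The Hprt knockout was compared with wild-type as the comparison of the lines without a Gtf2i mutation in their labels, which holds both the Hprt mutation and any difference of line. Fibroblast markers and interferon response genes were far lower in the Hprt knockout. The transcription factor gene Neurod1 was higher by log2 5.28 ± 0.07 (adjusted p = 5.91e-09, n = 2 against 2 arrays), Dll1 by 4.22 ± 0.16 and the tight junction gene Cldn4 by 3.24 ± 0.10. Cyyr1, Ccdc160, Frem2, Insm1, Car4, Ccno and Fgd5 rose by 3.18 to 3.72, all but Ccno from below the filter level in wild-type. The chemokine gene Cxcl5 was lower by log2 -9.48 ± 0.08 (adjusted p = 4.05e-09), the cytokine gene Il6 by -8.12 ± 0.11, Ifit1 by -7.74 ± 0.07 and Saa3 by -7.52 ± 0.12. Mmp13, Usp18, Lum, Ogn, Ifi202b and Fgf7 fell by -7.90 to -7.18. Apart from Saa3, these lower genes lay below the filter level in the Hprt knockout, as did Ifit3, Egr2, Tgfb3, Vcam1, Zic1 and Gda, named below. All 28 feeder fibroblast markers fell, also adjusted over the list alone, including Col1a1 (-5.72), Col3a1 (-5.20) and the lysyl oxidase gene Lox (-4.93) (adjusted p = 1.71e-21, and adjusted p = 0.00931 with an estimated correlation). The median of all tested genes was 0.16 and moved by -0.16 under cyclic loess, so list medians are again given relative to all genes. That of the feeder markers was -4.86, and again no list median changed sign under another scaling.

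Beside the feeder markers at -4.86, interferon response genes fell in 20 of 21 cases and rose in 1, also adjusted over the list alone (median -3.26, adjusted p = 2.27e-11, and adjusted p = 0.0189 with an estimated correlation). Usp18 was at -7.64, Ifit3 at -6.37 and B2m at -3.12. Immediate early genes fell with them in 13 of 18 cases and rose in 3, or 4 adjusted over the list alone (median -1.14, adjusted p = 0.000204, and adjusted p = 0.212 with an estimated correlation). Egr2 (-4.21), Ier3 (-4.01), Egr1 (-3.24) and Jun (-2.04) were lower. TGF-beta and BMP genes fell in 25 of 39 cases, 26 adjusted over the list alone, and rose in 11 (median -0.73, adjusted p = 3.02e-05, and adjusted p = 0.326 with an estimated correlation). Tgfbr2 (-3.98), Tgfb2 (-3.89) and Tgfb3 (-3.83) were lower and Lefty1 (3.08) higher. Hypoxia and glycolysis genes fell in 15 of 24 cases and rose in 5, 16 and 6 adjusted over the list alone (median -0.56, adjusted p = 0.00370, and adjusted p = 0.194 with an estimated correlation). Adm (-3.69) and P4ha1 (-1.85) were lower and Ddit4 (1.85) higher. Cell cycle genes rose in 24 of 29 cases and fell in 3, also adjusted over the list alone (median 0.38, adjusted p = 0.0164, and adjusted p = 0.194 with an estimated correlation). Cenpe (1.02) and Ccnb2 (0.81) were higher and Ccnd2 (-3.70) and Ccnd1 (-1.58) lower. PI3K-AKT genes had 9 rises and 15 falls among 29 (median -0.43, adjusted p = 0.0476, and adjusted p = 0.451 with an estimated correlation). Irs1 (-2.90) and Akt1 (-1.35) were lower and Inpp5d (1.73) higher. Cytoskeleton and adhesion genes had 9 rises and 13 falls among 22 (median -1.24, adjusted p = 0.0493, and adjusted p = 0.465 with an estimated correlation). Vcam1 (-6.15), Cd44 (-4.90) and Vim (-2.21) were lower and Cldn7 (2.88) higher. The counts of these last lists were the same adjusted over the list alone, and each call was lost in 8 other settings, with adjusted p up to 0.0953 and 0.244, respectively.

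Pluripotency genes had 16 rises and 6 falls among 24 (adjusted p = 0.296), with Fgf4 (1.98), Utf1 (1.48) and Prdm14 (1.43) higher. The primed epiblast list had 8 and 3 among 12 (adjusted p = 0.442), with Dnmt3a (2.70), Otx2 (2.57) and Dnmt3b (1.49) higher and Fst (-3.36) lower. The counts of these and of the other lists not called here were equal when adjusted over the list alone unless stated. Trophoblast genes had 8 and 1 among 10 (median 1.02, adjusted p = 0.0639), with Krt8 at 2.36 and Tfap2c at 2.27. Germ line genes had 12 and 3 among 16 (adjusted p = 0.151), with Mael at 1.85 and Dazl at -1.11. The 2-cell-like state had 1 and 4 among 5 (adjusted p = 0.0947), with Pramel7 at -1.92. Mesoderm had 1 and 3 among 10 (adjusted p = 0.250), with Bmp4 at -2.37. Neuroectoderm had 6 and 7 among 17 (adjusted p = 0.261), with Zic1 at -5.10 and a median of -0.17. Cholesterol synthesis had 9 and 2 among 16 (adjusted p = 0.442), with Dhcr7 at 1.16. The p53 targets had 12 and 4 among 19 (adjusted p = 0.339), with Fas at -3.05. Williams-Beuren interval genes had 12 and 2 among 23 (adjusted p = 0.250), with Mettl27 at 1.11 and Bud23 at 1.01. Primitive endoderm had 11 and 6 among 21 (adjusted p = 0.830), with Apoe at 2.22 and Sparc at -2.20. Its median and mean were positive and its test negative. Purine genes had 13 and 5 among 22 (adjusted p = 0.508), with Prps2 at 1.25, Adsl at 1.06 and Gda at -3.92. Their median and test were positive and their mean negative. Imprinted genes had 13 and 9 among 23 (adjusted p = 0.824), with Phlda2 at 1.78 and Igf2 at -4.55. Sex-linked genes had 3 and 2 among 6 (adjusted p = 0.874), with Xist at -3.01. In both lists the median was positive and the mean and test negative. Genes tied to TFII-I had 6 and 6 among 14 (adjusted p = 0.830), with Brca1 at 1.13 and Nsd1 at 1.14. Stress genes had 9 and 8 among 20 (adjusted p = 0.830), with Chac1 at 3.16 and Trib3 at 2.71. The medians of both lists (-0.14 and -0.13) and their tests were negative and their means positive. Ribosomal protein genes had 5 and 0 among 14, and none adjusted over the list alone (adjusted p = 0.830), with a median of -0.09 against a positive mean and test. By limma 9876 genes passed, 6409 higher and 3467 lower in the Hprt knockout, with 2660 differing at least 2-fold, 1161 higher and 1499 lower. Cyclic loess changed the split to 4709 and 4729.

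The trap line was also compared with wild-type, a comparison that mixes the trap, the Hprt mutation and any difference of line. All 16 cholesterol synthesis genes rose, also adjusted over the list alone, with a list median of 0.67 (quartiles 0.64 and 0.77), while most immediate early genes were lower. Mmp1a, a collagenase gene, was higher by log2 4.12 ± 0.19 (adjusted p = 2.21e-05, n = 2 against 2 arrays) with the other 3 groups below the filter level. The BMP ligand gene Bmp2 was higher by 2.82 ± 0.11 and Neurod1 by 2.43 ± 0.07, and Cd53, Vstm2a, S100a8, Gpnmb, Mmp10, Nlrp4f and Pnma2 rose by 2.26 to 2.85. Egr2 was lower by log2 -4.00 ± 0.14, Ccn2 by -3.71 ± 0.06, the smooth muscle calponin gene Cnn1 by -3.43 ± 0.06, Ccn1 by -3.34 ± 0.06 and Ankrd1 by -3.14 ± 0.05. Asb5, Dcaf8l, Gjb2, Chsy3 and Rspo2 fell by -3.61 to -2.80. Egr2, Dcaf8l, Gjb2 and Chsy3 lay below the filter level in the trap line, and Vstm2a did so in wild-type. Immediate early genes fell in 13 of 18 cases, 15 adjusted over the list alone, and rose in 1 (median -0.51). Of 28 feeder markers 16 fell and 2 rose, 16 and 3 adjusted over the list alone (median -0.47). Thbs1 (-1.97), Tagln (-1.70), Acta2 (-1.55) and Col1a1 (-1.22) were lower and S100a4 (0.80) and Dcn (0.50) higher. These 6 genes were chosen after their values were seen. Interferon response genes fell in 11 of 21 cases and rose in 4, also adjusted over the list alone (median -0.46). Pluripotency genes rose in 15 of 24 cases and fell in 2, also adjusted over the list alone (median 0.26). The p53 targets rose in 12 of 19 and fell in 2, also adjusted over the list alone (median 0.29). Primitive endoderm genes fell in 12 of 21 cases and rose in 4, also adjusted over the list alone (median -0.34). The 24 hypoxia and glycolysis genes held 3 rises and 10 falls, 3 and 11 adjusted over the list alone (median -0.16). No ribosomal protein gene passed among 14. These lists were counted in this comparison and not put to a set test. By limma 5673 genes passed, 3662 higher and 2011 lower in the trap line, with 473 differing at least 2-fold, 215 higher and 258 lower. Cyclic loess changed the split to 3036 and 2566.

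**Figure D2:**
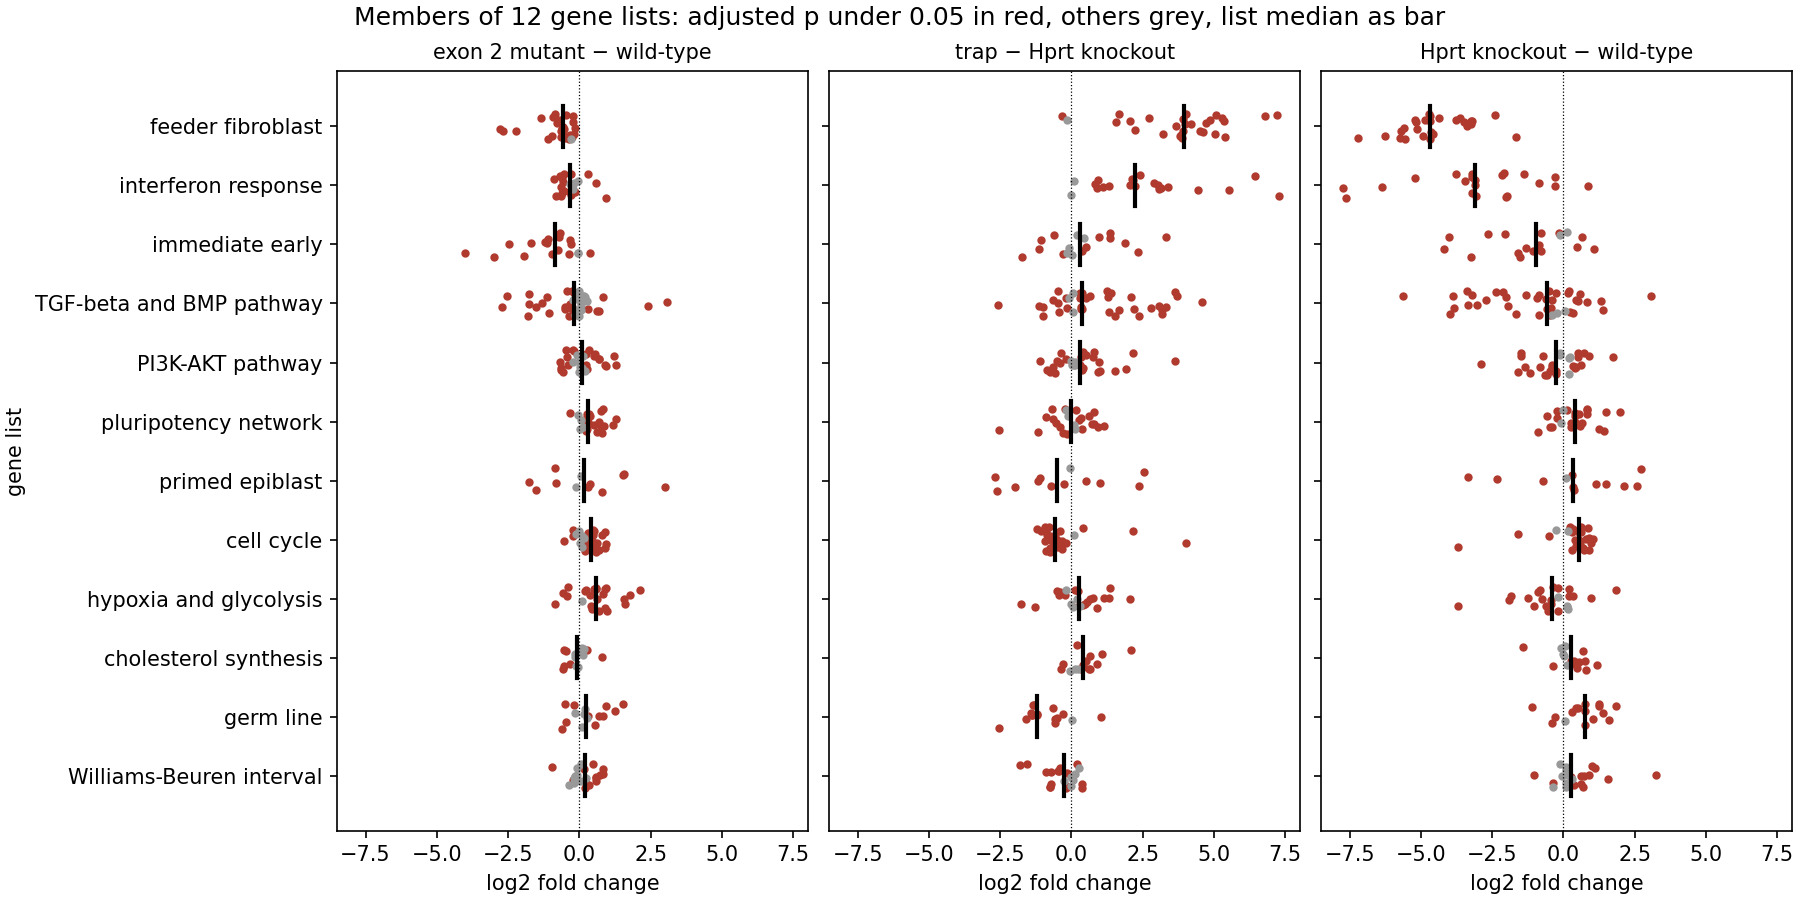
Log2 fold change (horizontal axis) of the tested members of 12 gene lists (vertical axis) in 3 comparisons, with red points for members past adjusted p of 0.05, grey points for the others and a black bar for the list median. The feeder fibroblast median lay at -0.59 for exon 2 mutant minus wild-type, 3.95 for trap minus Hprt knockout and -4.70 for Hprt knockout minus wild-type.

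Changes in the exon 2 mutant against wild-type and in the trap line against the Hprt knockout were set side by side. Both lines carry a mutation of Gtf2i, and the comparisons share no arrays. They do share each gene's estimate of the spread, so their calls are not independent. The counts given below for independent lists are therefore only a rough guide. Genes that rose in both included Mid1, a microtubule-associated ubiquitin ligase gene (3.16 ± 0.09 and 2.83 ± 0.09), the channel gene Trpm1 (2.64 and 1.64) and the neuronal enolase gene Eno2 (1.18 and 1.66). Lrrc34 (1.22 and 1.18), Crxos (1.25 and 1.11) and the transcription factor gene Snai2 (1.01 and 3.56) also rose in both, and Cxcl3, Zfp619, Tmem74 and Msrb2 did so as well. Eno2, Cxcl3 and Tmem74 lay below the filter level in the Hprt knockout, Cxcl3 also in the trap line and Tmem74 in wild-type. Genes that fell in both included Srgn (-2.22 ± 0.08 and -2.32 ± 0.08), the keratin genes Krt8 (-1.69 and -2.83) and Krt18 (-1.32 and -3.07), Fgfbp1 (-2.22 and -1.64), Pth1r (-1.21 and -1.30) and Cited1 (-1.17 and -1.02). The primitive endoderm transcription factor Sox17 (-1.15 and -1.24), the laminin gene Lama1 (-1.50 and -2.00) and Cubn (-1.40 and -2.64) and Amn (-1.05 and -1.79), whose products form an endocytic receptor, fell in both, with the feeder markers at -0.59 and 3.95. The primitive endoderm list as a whole went both ways in trap against Hprt knockout, with 7 rises and 10 falls among 21, and camera did not call it (adjusted p = 0.806). Sox17 and Cited1 lay below the filter level in the exon 2 mutant. Altogether 944 genes changed the same way, 440 up and 504 down, where independent lists would share 1193 and 1332. In opposite directions 5173 genes passed. Of these 3164 were up in the exon 2 mutant and down in the trap line, where independent lists would share 1874, and 2009 the other way, where they would share 848. Across the 13819 genes, which are not independent replicates, the fold changes correlated at Pearson r = -0.50 and Spearman rho = -0.54. With the controls exchanged, an alternative chosen after the data were seen, the exon 2 mutant against the Hprt knockout and the trap line against wild-type correlated at r = -0.22.

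The difference between both effects was tested by subtracting the trap effect from the exon 2 effect. It also holds any difference of line and of feeder signal between the groups, which cannot be told apart from the mutations. It was largest on the positive side for Chac1 (6.77 ± 0.11), Lefty1 (5.66 ± 0.07), Myb (5.43 ± 0.27), Trib3 (5.12 ± 0.10) and Ccdc160 (5.07 ± 0.09). On the negative side it was largest for Cxcl5 (-9.20 ± 0.12), Saa3 (-8.87 ± 0.17), Lcn2 (-8.63 ± 0.18), Mmp13 (-8.21 ± 0.27) and Ereg (-8.20 ± 0.12). Of these, Myb and Ccdc160 lay below the filter level in wild-type and Cxcl5, Lcn2, Mmp13 and Ereg in the Hprt knockout. Gtf2i itself differed by 1.18 ± 0.07 (adjusted p = 8.03e-06). By limma 9626 genes passed, 5889 with the higher value in the exon 2 effect and 3737 with the lower, and 4045 differed at least 2-fold, 2131 higher and 1914 lower. The median of all genes was 0.16 and moved by -0.19 under cyclic loess, which changed the split to 4514 and 4864.

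**Figure D3:**
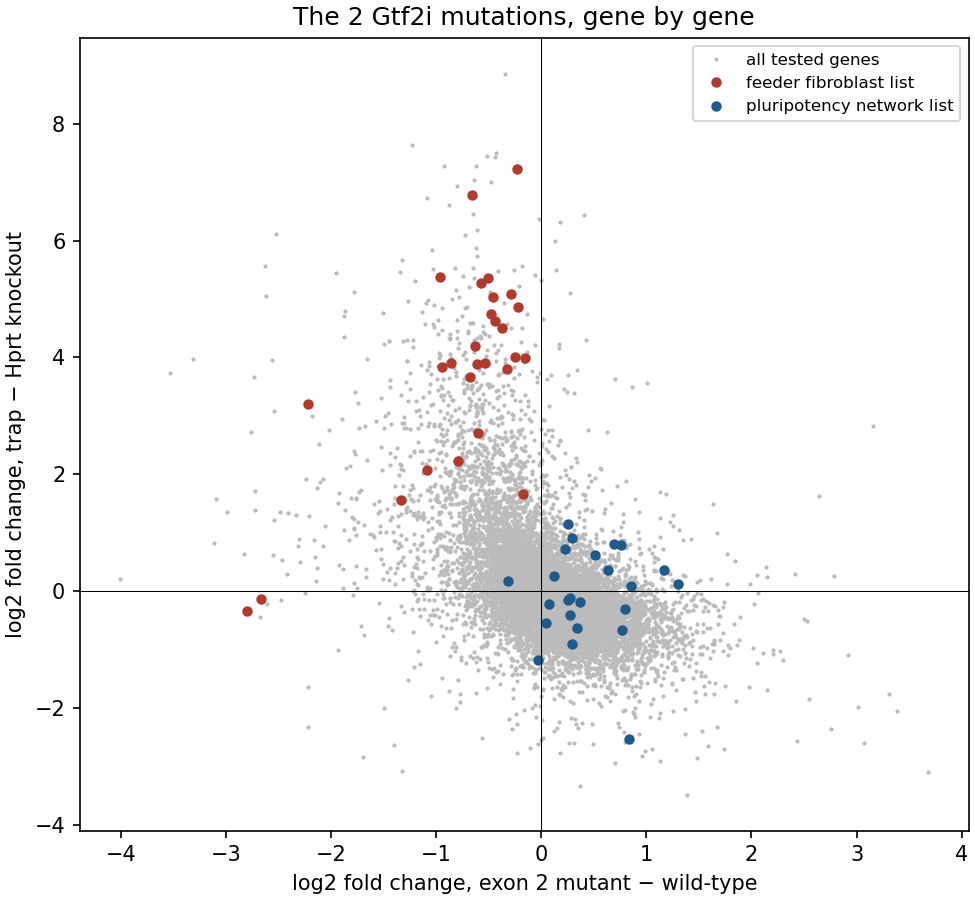
Log2 fold change of each tested gene in the exon 2 mutant against wild-type (horizontal axis) and in the trap line against the Hprt knockout (vertical axis), with feeder fibroblast markers in red, pluripotency genes in blue and all others in grey. Across the genes Pearson r was -0.50, with most feeder markers at the upper left (list medians -0.59 and 3.95).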

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

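All tests of explanations in this part, and the list test of the difference between both effects, were chosen after the results were seen. The effects of both Gtf2i mutations, each against the control used here, differed for 9626 of 13819 genes by the limma test of the difference itself. The labels do not name the wild-type line, and the Hprt knockout was low in feeder markers. Differences of line and of feeder signal therefore enter this contrast and cannot be told apart from the mutations. The gene with the largest positive difference (exon 2 effect minus trap effect) was Chac1, at log2 6.77, followed by Lefty1 at 5.66, Myb at 5.43, Trib3 at 5.12 and Ccdc160 at 5.07. The largest negative differences were those of Cxcl5 at -9.20, Saa3 at -8.87, Lcn2 at -8.63, Mmp13 at -8.21 and Ereg at -8.20. Of these genes Myb and Ccdc160 lay below the filter level in wild-type and Cxcl5, Lcn2, Mmp13 and Ereg in the Hprt knockout. Gtf2i itself differed by 1.18. Camera on this difference, at the preset correlation alone, called the feeder fibroblast list lower (adjusted p = 1.07e-18), as it did interferon response (adjusted p = 4.73e-09), the TGF-beta and BMP pathway (adjusted p = 0.000320), immediate early genes (adjusted p = 0.000320) and cholesterol synthesis (adjusted p = 0.00721). It called cell cycle (adjusted p = 0.000434) and germ line (adjusted p = 0.00721) higher.

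Feeder fibroblast markers were lowest in the Hprt knockout arrays, with Col3a1 at a mean log2 intensity of 9.59 there against 14.79 in wild-type. Of 28 tested markers 26 lay below each of the other 3 groups, a count that restates the pattern. As a test, 30 other fibroblast genes outside the lists, written from general knowledge, were examined. All 30 fell against each group, with medians of -3.77, -3.55 and -3.25 against wild-type, trap and exon 2 mutant. The quartiles for the last were -4.18 and -2.23. Fewer feeder cells in the RNA of the Hprt knockout arrays would give this fall. These genes belong to the same cell type as the markers. Their fall therefore does not tell fewer feeder cells from lower expression of fibroblast genes. All but 1 of the markers, 27, still lay above the filter level in those arrays, and 1, Dcn, is also held by another list. The Hprt mutation as the cause is argued against by the trap line, which carries it by its label and had a feeder list median of -0.47 against wild-type (quartiles -0.93 and -0.10), where the Hprt knockout had -4.70. A difference between the parent lines stays open, untested, and every change between trap and Hprt knockout or between Hprt knockout and wild-type is read beside this difference in fibroblast signal.

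The matrix genes Ccn1 and Ccn2 and 13 of 18 immediate early genes had their highest mean in the wild-type arrays, and 10 of the 18 were lower in each of the other 3 groups by limma. Whether fewer feeder cells could be the whole cause was asked of Ccn1 and Ccn2, which are themselves in the feeder list. Their smaller fall was -3.34 in the trap line and -2.67 in the exon 2 mutant, further than any of the other 26 markers, whose largest falls were -1.97 and -2.22 (Thbs1). Both genes were picked after their large falls were seen, so this ranking restates the choice. Ccn2 was at 10.68 in the trap line and 11.03 in the Hprt knockout, and Ccn1 at 9.36 and 9.50. Feeder markers were higher in the trap line than in the Hprt knockout, by a list median of log2 3.95. For Ccn1 and Ccn2 in the trap line, this argues against fewer feeder cells as the whole cause. In the exon 2 mutant both genes lay above the Hprt knockout, and the question is not decided there. For the immediate early genes fewer feeder cells in the trap arrays stay open, since the immediate early median against wild-type was -0.51 (quartiles -0.74 and -0.32) beside a feeder median of -0.47, and these ranges overlap. Of the feeder markers there 16 fell, 2 rose and 10 did not pass. For the exon 2 mutant the same explanation stays open too, since the immediate early median was -0.87 (quartiles -1.59 and -0.34) beside a feeder median of -0.59, and these ranges overlap. An effect of the Gtf2i mutations is not excluded either: the immediate early median in the Hprt knockout, which has no Gtf2i mutation, was -0.98 against wild-type (quartiles -1.93 and -0.13), but those arrays also had a feeder median of -4.70. How the wild-type cells were handled before lysis is not given in the sources used here.

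Gtf2i was higher, not lower, in the heterozygous exon 2 mutant than in wild-type. More feeder RNA in the wild-type arrays, diluting that of the stem cells, may account for part of it: pluripotency genes rose by a median of 0.32 (quartiles 0.25 and 0.76) beside 0.36 and 0.64 for the Gtf2i probe sets above the filter level, so the test leaves this open. Exchanged labels of the trap and wild-type arrays would not account for it. Gtf2i on its brightest probe set was at 10.09 in the trap line and 10.12 in wild-type, both below the 10.48 of the exon 2 mutant. Hprt, which was lower in the arrays labelled trap by log2 -1.34, also argues against that exchange. Exchanged labels of the exon 2 mutant and wild-type arrays were not tested. A probe outside exon 2, or a change of expression from either allele, was not tested.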

How the results depend on the processing

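The alternatives with exchanged controls, with crossed replicate numbers and without the Hprt knockout arrays were chosen after seeing the data. Over the alternatives of scaling, arrays in the fit, prior, block and arrays left out, the named genes held their direction and side of the threshold in 6463 comparisons of gene and setting, lost the call in 155, gained it in 35 and reversed in 1. Over these and the filters and the mean of probe sets, lists called in the report by camera at the preset correlation held the call in 435 and lost it in 23. That tally leaves out the estimated correlation, fry and lists gained. The reversed value was Dnajc30 in the Hprt knockout against wild-type, at 0.25 in the report and -0.0059 under cyclic loess, which also moved the median of all genes there by -0.16. Hprt in the exon 2 mutant against wild-type, at 0.17, missed the threshold when adjusted over all probe sets (adjusted p = 0.105) and passed with a trended robust prior (0.17, adjusted p = 0.00427).

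Counts of changed genes moved by more than 1.5 times with all probe sets, where more items are tested, and with stricter thresholds. With all probe sets they were 13335 for exon 2 mutant against wild-type, 16944 for trap against Hprt knockout, 18434 for Hprt knockout against wild-type, 10108 for trap against wild-type, 17672 for the difference of effects and 1502 changed the same way. With at least 2-fold change they were 750, 2104, 2660, 473, 4045 and 23 in the same order. An adjusted p under 0.01 left 3570 for trap against wild-type and 470 changed the same way. Leaving out each array in turn gave 6114 to 7576, 8310 to 9592, 9077 to 10009, 3913 to 5799, 9033 to 9436 and 697 to 860, again in that order. Under cyclic loess 6763 of the 7674 genes called in the exon 2 mutant, 7917 of 9449, 8171 of 9876, 4926 of 5673 and 8247 of 9626 kept their call and sign. With the mean of a gene's probe sets 6289, 8352, 8762, 4442 and 8533 kept them, and 16, 32, 35, 12 and 26 were called in the opposite direction. Without the Hprt knockout arrays the exon 2 mutant had 7576 calls and 9 lists and the trap line 5538 calls against wild-type.

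The correlation of both mutations across genes moved by more than 0.0146, its SD over choices of 1 array per group, with no filter (-0.484), a filter at the 60th percentile (-0.522), all probe sets (-0.477) and exchanged controls (-0.215), and leaving out an array gave -0.505 to -0.485; the cause was not tested. With exchanged controls 906 genes were higher and 508 lower in both, where independent lists would share 912 and 730. Called gene lists went from 10, 9 and 8 (exon 2 mutant, trap against Hprt knockout, Hprt knockout against wild-type) to 1, 2 and 2 with an estimated correlation and to 23, 23 and 25 with fry, and leaving out an array gave 9 to 10, 9 and 6 to 9. Replicate numbers as given did not pair the arrays: deviations of same-numbered arrays correlated at -0.28 to 0.17 between groups. Crossing the numbers of the exon 2 mutant and Hprt knockout arrays turns every one of these correlations positive. A factor shared by the groups is therefore not excluded. With the replicate block 7248, 9127, 9620, 5170 and 9361 genes passed, 831 the same way, and with crossed numbers 8077, 9800, 10154, 6078 and 9938, with 1080 the same way. Where a group lay below the filter level, a fold is limited by array background.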

Other observations

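The overlap of genes changed in the exon 2 mutant and in the trap line, both against wild-type, was counted after the data were seen. Dpys, a pyrimidine-degrading enzyme gene, was higher in both lines (log2 2.15 and 2.07), as were Patl2 (2.21 and 1.77), Neurod1 (1.48 and 2.43), Trpm1, Mid1 and Ccdc160 (3.30 and 1.72). Egr2 (-4.00 and -4.00), Ccn2 (-2.80 and -3.71), Ccn1 (-2.67 and -3.34), the activin subunit gene Inhba (-2.54 and -2.54) and Ankrd1 (-2.42 and -3.14) were lower in both. Egr2 lay below the filter level in both lines and Ccdc160 in wild-type, so these folds depend on the array background. Ccn1, Ccn2 and Ankrd1 are known targets of the YAP and TAZ coactivators. The Hprt knockout, which has no Gtf2i mutation, went the same way against wild-type for all of these except Mid1 (-1.03), though for Trpm1 only by 0.33. It also passed the same way for 1874 of the 2123 genes higher in both lines and for 1006 of the 1243 lower in both. All of these comparisons use the same wild-type arrays, and over all 13819 genes 6409 were higher and 3467 lower in the Hprt knockout, so the counts do not show which group stands apart. They do not tie the changes to Gtf2i. Both lines stood below wild-type in feeder markers, with list medians of -0.59 and -0.47. Of the genes tested 2123 were higher and 1243 lower in both lines, where independent lists would share 1189 and 464, and 289 and 471 went opposite ways. Fold changes correlated at 0.53, against a mean of 0.50 in 100 simulations of unchanged groups against the same wild-type arrays, and their covariance was 0.110 against 0.00562, a difference of 0.104. Unchanged groups passed too few genes at this threshold to share any (highest overlap 0 in either direction), so the simulated overlap does not measure what the shared arrays add to the counts. The 2 wild-type arrays are too few to split between the comparisons, so part of the excess over independent lists may come from sharing them.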
